A study of Mus musculus with 2 samples.

How the data were processed

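DNase-seq was analysed in 2 libraries from thymus tissue of male B6CASTF1/J mice aged 36 days. The labels give the libraries as separate biological replicates, but both carry the same donor identifier, so the number of mice is not settled. Per the labels the reads were placed on mm10. The deposited peak lists give in column 7 the signal of each peak. The deposited FDR cut rate tables give in column 5 a p-value-like FDR per interval, and only intervals below 0.05 are listed (highest 0.0499 and 0.0500). The deposited footprint lists give in column 5 a score, which was 0.01 in every row and could not be used to rank footprints. Per the deposited notes all lists derive from the filtered alignment of the same library, and the footprints also from the FDR table. The aligner, the peak and footprint callers, their thresholds and the scaling of the signal are not given in the sources used here. The signals were whole multiples of 1 step per library, 0.00784 in the library labelled replicate 1 and 0.00771 in the library labelled replicate 2 (within 0.05 steps in 100% of peaks). Depth per library is unknown, so intervals cover counting of peaks or sequence positions only.

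Each library has 2 deposited peak lists. Every peak of the shorter list held an interval with an FDR of at most 0.000999 in the library labelled replicate 1 and 0.000994 in the library labelled replicate 2, and this list was the main one. The longer lists held 126824 and 88164 peaks and overlapped 97.7% and 98.6% of the shorter. The shorter lists covered 19.6 and 13.0 Mb with a median width of 200 bp in both. All peaks lay within the chromosome ends of GRCm38, the assembly of the reference.

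The reference was GRCm38.p6 with the GENCODE vM21 annotation and the RefSeq tRNA genes. A promoter was the sequence within 1 kb of any of 132629 transcript starts. Peaks were shared when they overlapped by at least 1 bp, and overlapping pairs were merged into regions. As a control the other library's peaks were moved by 1 Mb. A region was placed at a promoter, else in an exon, an intron or between genes by its midpoint. Genes were 21911 protein-coding genes. Distal peaks were those beyond the promoter windows, counted over the gene and 20 kb on either side. Footprints placed at random within the same library's peaks (10 placements) served as control.

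The 17 gene lists (244 genes), the rule for named genes, the 26 consensus sequences and the tests were fixed before the data were examined. The lists were T cell receptor and coreceptor, T lineage transcription factor, thymocyte development, effector T cell, B cell, myeloid and dendritic cell, erythroid, thymic epithelium, endothelium, fibroblast and mural cell, liver, neuron, skeletal muscle, pluripotency and germ line, developmental transcription factor, housekeeping and cell cycle. Promoters were compared by Fisher's exact test, two-sided, members against all other protein-coding genes. Distal counts were compared by a two-sided permutation test of the list median against 10000 random lists matched for domain length. Both were adjusted by Benjamini-Hochberg over the 17 lists. A gene counted when both libraries had the peak. Genes are not independent replicates. Motifs were counted on both strands in footprints and in the rest of the peak sequence, with Fisher's exact test on positions per library, adjusted over the 26, and called when both libraries passed. Controls were the consensus sequences reversed without complementing, for the 20 of 26 that are not their own reverse complement. NRF1, AP-1, CRE, STAT, MEF2 and GRE had no control.

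Named by rule were, per list, up to 4 genes with the highest mean percentile of promoter signal, up to 3 members with no promoter peak, and up to 3 per library with a promoter peak in 1 library only. The rule also named the 10 densest domains of at least 50 kb, the 10 strongest shared regions, the 10 strongest distal ones, the 6 called motifs with the highest ratio and every motif lower in both libraries. From these the text gives a selection. Bcl11b is named as the exception in its list.

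The 2 libraries were found to differ at T cell genes once the values were seen. The comparison of the lists between libraries (counts of genes open in 1 library only, differences in distal peaks), the test of motif ratios between libraries, the motifs of unshared distal peaks and the motif results of each library alone were added at that point. So were 10 further tissue lists (125 genes), tested with the liver, neuron and skeletal muscle lists as 13 lists of other tissues. The new lists were pancreas, stomach, lung, heart, kidney, small intestine, adrenal gland, adipose tissue, epidermis and glia. Their outcomes were not known when they were written, but the distal counts of the 3 older ones were. Further copies of regions were sought with blastn (at least 90% identity over 80% of the length).

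Alternatives were promoter windows of 500 bp and 2500 bp, domain flanks of 5 and 100 kb, the stronger 50% of peaks, equal numbers of peaks, the longer lists, overlap of at least 50% of both intervals, the gene 5' end as only start, shared footprints, 20 bp added to footprints, background within 50 bp, distal peaks only and each library alone. No paired analysis was possible because the libraries form 1 group. No model across libraries was fitted.

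The steps were tested on simulated data. With 95% against 55% of promoters open, 90.2% of simulated lists were recovered and 0.714% of the unchanged lists were called (21911 genes, 200 sets). For 3-fold more distal peaks 98.3% were recovered and 0.714% called falsely (21911 genes, 20 sets). The simulated distal counts were independent Poisson draws not matched to the deposited peaks, so recovery in the shared regions can be lower. A consensus planted at a ratio of 2 was measured at 1.99. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, matplotlib 3.10.9, bedtools 2.31.1, samtools 1.23.1 and blastn 2.17.0.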

Results

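DNase-seq maps chromatin that is open to cutting by the nuclease DNase I. It was measured in 2 libraries from thymus tissue of male mice of the F1 hybrid strain B6CASTF1/J, aged 36 days. The 2 libraries form 1 group and are labelled replicate 1 and replicate 2. The labels give them as separate biological replicates, although both carry the same donor identifier. The deposited files hold 2 peak lists, 1 footprint list and 1 table of false discovery rates (FDR) per library. None of them holds read counts, so the depth of each library is unknown and no limit from counting reads can be given. The shorter peak list held 85367 peaks in the library labelled replicate 1 and 60644 in the library labelled replicate 2. With 1 group of 2 libraries no test with libraries as replicates was possible. The tests below compare genes or sequence positions, within a library or between the 2 libraries. Their p-values and intervals do not cover variation between libraries. All coordinates are on mm10.

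The question of the first comparison was which genes of the thymocyte lineage and of other cell types had open promoters, meaning a peak within 1 kb of a transcript start. The 2 libraries gave opposite answers for the genes of the T cell receptor complex and its coreceptors. Of 19 such genes, 18 (94.7%) had an open promoter in the library labelled replicate 2 and 4 (21.1%) in the library labelled replicate 1. Of all 21911 protein-coding genes, 13158 (60.1%) and 13822 (63.1%) had one. The list was thus above other genes in the library labelled replicate 2 (Fisher's exact test, two-sided, adjusted p = 0.00624) and below them in the library labelled replicate 1 (adjusted p = 0.00219). The direction of this result therefore depends on whether the library labelled replicate 1 is counted: by the rule fixed in advance, a peak in both libraries, 4 of 19 (21.1%) were open (exact adjusted p = 0.00386). With the longer peak lists 36.8% were open in both libraries and the list no longer passed (Fisher's exact test, adjusted p = 0.0592). None of the 19 was open in the library labelled replicate 1 alone and 14 were open in the library labelled replicate 2 alone, against 1404 and 740 of all genes (Fisher's exact test of these counts, two-sided, adjusted p = 5.34e-06).

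The 14 genes included Cd3d, Cd3e, Cd3g, Cd8a and Cd8b1, which encode CD3 and CD8 chains. Peak signal in the library labelled replicate 2 was 10.2 at Cd8b1 (ENSMUSG00000053044.8, chromosome 6, 71322788 to 71337494), 10.1 at Cd8a and 10.9 at Lat, an adaptor of receptor signalling, and none of these 3 had a promoter peak in either list of the library labelled replicate 1. At Cd3e (ENSMUSG00000032093.7, chromosome 9, 44998740 to 45009627), picked after its values were seen, the signal was 5.66 against no peak. The 4 genes open in both libraries were Lck, Cd247, Cd27 and Cd28. With the gene 5' end as only start, 0 of the 19 were open in both (Fisher's exact test, adjusted p = 1.52e-05). These 4 thus counted through other transcript starts in at least 1 library. Lck (ENSMUSG00000000409.14, chromosome 4, 129548344 to 129573641), the kinase bound to the coreceptors, had a mean signal of 8.78 ± 4.33 (SD, n = 2). Cd247, Cd27 and Cd28 had 0.933, 0.706 and 0.337 in the library labelled replicate 1 and 4.49, 5.72 and 4.05 in the library labelled replicate 2. How the authors scaled the signal is not given in the sources used here, so signals are compared only within a library. Across shared regions the signal was a median of 1.34 times as high in the library labelled replicate 2. Means and SDs over the 2 libraries here and below only summarise 2 values, and the SDs include any difference in scale. Trat1 had no promoter peak in either library.

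Genes of thymocyte development were also open more often in the library labelled replicate 2. Of 16, 15 were open in the library labelled replicate 2 (exact adjusted p = 0.0120) and 8 in the library labelled replicate 1 (adjusted p = 0.371), and 7 were open in the library labelled replicate 2 alone against 0 in the other (adjusted p = 0.00487). Rag1 and Rag2, which encode the V(D)J recombinase, were among the 7 and were picked after their values were seen, with signals of 4.75 and 3.81. Open in both libraries were, among others, Klf2 with 8.37 ± 1.45 (SD, n = 2), Hes1 with 6.44 ± 0.157 (SD, n = 2), Notch1 with 5.97 ± 3.81 (SD, n = 2) and Cd1d1 with 4.35 ± 3.76 (SD, n = 2). Dntt, which encodes terminal transferase, had no promoter peak in either of the shorter lists and a signal of 2.09 in the longer list of the library labelled replicate 2.

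Promoters of T lineage transcription factors were open in both libraries, 17 of 18 in the library labelled replicate 1 (exact adjusted p = 0.0115), 18 of 18 in the library labelled replicate 2 (adjusted p = 0.00109) and 17 of 18 (94.4%) in both (adjusted p = 0.00206). Among the stronger 50% of peaks 72.2% were open in both libraries and the list no longer passed (exact adjusted p = 0.0711). Among the strongest were Ets1 with 14.5 ± 9.97 (SD, n = 2), Tcf3 with 7.87 ± 3.86 (SD, n = 2) and Id3 with 7.82 ± 5.51 (SD, n = 2). The exception was Bcl11b, a regulator of T cell commitment, with a signal of 9.04 in the library labelled replicate 2 and no promoter peak in the library labelled replicate 1. Effector T cell genes were open in 7 of 18 cases in the library labelled replicate 2 (exact adjusted p = 0.139) and in 1 in the library labelled replicate 1 (adjusted p = 8.67e-06), namely Foxp3, which was open in both with 6.77 ± 4.07 (SD, n = 2). Of these genes 6 were open in the library labelled replicate 2 alone and 0 in the other alone (exact adjusted p = 0.00945).

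**Figure D1:**
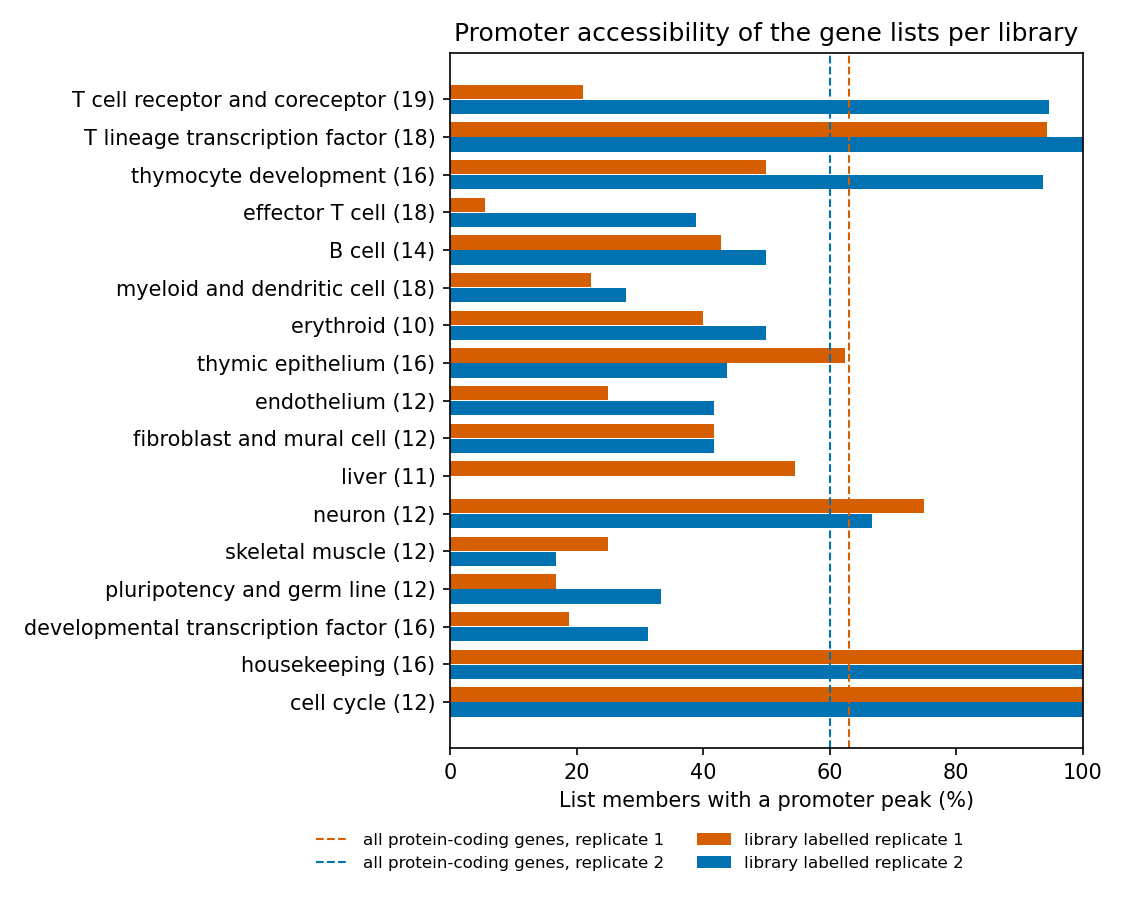
Share of the genes of each list (percent) with a peak within 1 kb of a transcript start, for each of 17 lists and each library. T cell receptor and coreceptor genes reached 94.7% in the library labelled replicate 2 and 21.1% in the library labelled replicate 1, and the liver list 0% and 54.5%.

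Of the lists of other cell types none passed the test of genes open in 1 library only. Of 11 liver genes, 6 had an open promoter in the library labelled replicate 1 (exact adjusted p = 0.588 against other genes) and 0 in the library labelled replicate 2 (adjusted p = 0.000700). The 6 against 0 did not pass when set against the balance of all genes (exact adjusted p = 0.345). Their signals in the library labelled replicate 1 were 3.45 at Hnf4a, a regulator of liver genes, and 0.408 at Alb, and these genes were picked after their values were seen. No liver gene was open in both libraries (exact adjusted p = 0.000570), and with 2500 bp windows 27.3% were (exact adjusted p = 0.0533). Genes of thymic epithelium were open in 10 of 16 cases in the library labelled replicate 1 and in 7 in the library labelled replicate 2, and 6 in both (exact adjusted p = 0.165). They included Ccl25, a chemokine that attracts thymocytes, with 12.7 ± 5.72 (SD, n = 2), and Prss16, a thymus-specific protease, with 4.14 ± 0.158 (SD, n = 2). Foxn1, the regulator of thymic epithelium, Krt5 and Krt14 had no promoter peak in either. Promoter peaks of list members found in the library labelled replicate 1 alone were strongest at the epithelial gene Cldn3 with 5.26, at Gata4 with 4.48 and at Esam with 4.05.

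Housekeeping and cell cycle genes had open promoters throughout, 16 of 16 (exact adjusted p = 0.000622) and 12 of 12 (adjusted p = 0.00386) in both libraries, led by Rplp0 with 22.1 ± 10.3 (SD, n = 2) and Mcm5 with 14.6 ± 7.44 (SD, n = 2). Fewer genes than the 56.7% of all genes were open in both libraries for myeloid and dendritic cells (3 of 18, exact adjusted p = 0.00278), endothelium (2 of 12, adjusted p = 0.0104), skeletal muscle (2 of 12, adjusted p = 0.0104), pluripotency and germ line (1 of 12, adjusted p = 0.00206) and developmental transcription factors (1 of 16, adjusted p = 0.000286). The B cell (6 of 14, exact adjusted p = 0.475), erythroid (3 of 10, adjusted p = 0.148), fibroblast and mural cell (3 of 12, adjusted p = 0.0543) and neuron lists (7 of 12, adjusted p = 1.00) did not pass. In the library labelled replicate 2 alone the endothelium (41.7%, exact adjusted p = 0.293) and pluripotency lists (33.3%, exact adjusted p = 0.130) no longer passed. The myeloid and dendritic cell list no longer passed with 2500 bp windows (33.3%, exact adjusted p = 0.0502), and the fibroblast list passed with the gene 5' end alone (16.7%, exact adjusted p = 0.0286). Open in both were, for example, Vpreb1 with 5.74 ± 1.74 (SD, n = 2), Cebpa with 8.01 ± 4.71 (SD, n = 2), Col1a1 with 4.99 ± 0.0721 (SD, n = 2) and Ckm with 7.42 ± 3.30 (SD, n = 2). No promoter peak was found in either library at Cd79a of B cells, Csf1r of macrophages, Hba-a1 of erythroid cells, Cdh5 of endothelium or Nanog of pluripotent cells.

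Distal peaks, more than 1 kb from any transcript start and in a gene's body or within 20 kb of it, set the 2 libraries apart at receptor genes and T lineage transcription factors. In the library labelled replicate 2 the median number per gene was 7 for T cell receptor and coreceptor genes, 11 for T lineage transcription factors and 3.5 for thymocyte development, against medians of 1, 1.5 and 1 in random lists matched for domain length (permutation test, two-sided, adjusted p = 0.00170, 0.00170 and 0.00680). In the library labelled replicate 1 the medians were 2, 3 and 2.5 and none of the 17 lists passed (permutation test, adjusted p = 1.00 for each of these 3). The difference per gene, replicate 2 minus replicate 1, had a median of 5 for receptor genes and 6.5 for transcription factors (permutation test, adjusted p = 0.00170 for each, from the smallest p of 0.0002 that the permutations can give) and of 0 for thymocyte development (adjusted p = 1.00). When only regions with a peak in both libraries were counted, the medians were 1, 1.5 and 1 and none of the 17 lists passed (permutation test, adjusted p = 1.00 for each of these 3).

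Single genes, picked after their values were seen, show the size of the difference. Tcf7 (ENSMUSG00000000782.15, chromosome 11, 52252371 to 52283014), a transcription factor of T lineage specification, had 60 distal peaks in the library labelled replicate 2 and 6 in the library labelled replicate 1. The counts were 38 and 0 at Cd8b1, 24 and 2 at Bcl11b, 22 and 3 at Ets1, 16 and 0 at Cd8a, and 16 and 1 at Satb1. Some genes went the other way, with 8 and 15 at Notch1, 2 and 11 at Hes1, and 2 and 8 at Ptcra.

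**Figure D2:**
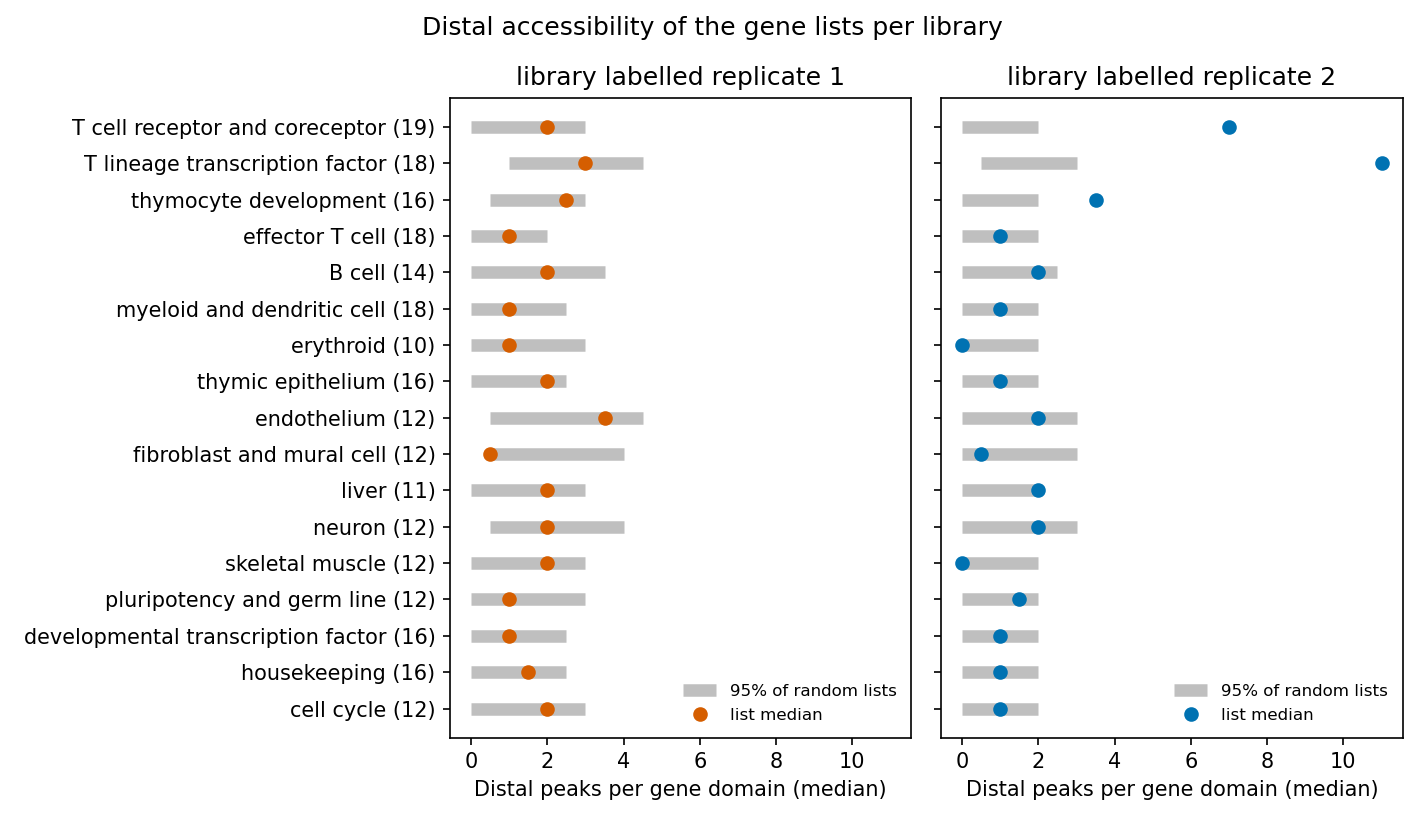
Median number of distal peaks per gene domain for each of 17 lists in each library, beside the range of 95% of the medians of random lists matched for domain length. T lineage transcription factors had 11 in the library labelled replicate 2 and 3 in the library labelled replicate 1.

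The next comparison asked how far the 2 libraries held the same sites. Of the peaks of the library labelled replicate 1, 36784 (43.1%, 95% Wilson interval 42.8 to 43.4) overlapped a peak of the other, and of those of the library labelled replicate 2, 36754 (60.6%, 60.2 to 61.0). After the other library's peaks were moved by 1 Mb, 1.51% and 2.15% overlapped. The share rose with signal, from 12.6% in the weakest 10% of the peaks of the library labelled replicate 1 to 90.4% in the strongest, and from 37.6% to 98.5% in the library labelled replicate 2. Of the peaks without a partner, 11.1% and 15.1% overlapped a peak of the other library's longer list.

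**Figure D3:**
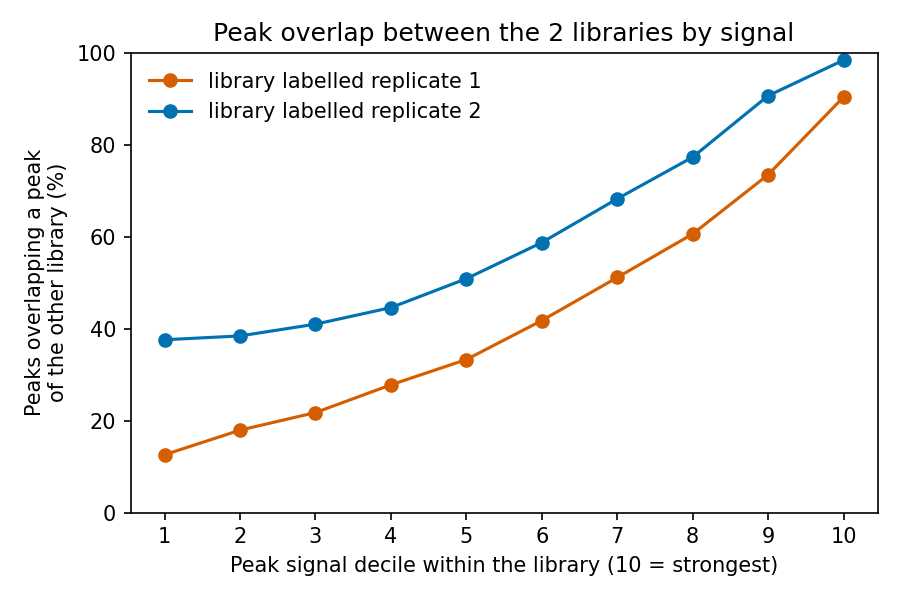
Share of the peaks of each library (percent) that overlap a peak of the other, in 10 equal bins of peak signal within the library. It rose from 12.6% to 90.4% in the library labelled replicate 1 and from 37.6% to 98.5% in the library labelled replicate 2.

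Overlapping peaks merged into 35217 shared regions. Across these regions, which are not independent replicates, the signals of the 2 libraries had a Spearman correlation of 0.759 and a Pearson correlation of the log10 values of 0.757. Promoters held 51.5% of the shared regions and 6.03% of the genome, introns 22.0% and 38.3%, exons 3.81% and 3.07%, and intergenic sequence 22.8% and 52.6%. Peaks without a partner were less often at promoters, 25.5% in the library labelled replicate 1 and 24.9% in the library labelled replicate 2.

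The strongest shared region lay on chromosome 17 (39846781 to 39846920), with signals of 117 and 93.3 in the libraries labelled replicate 1 and 2. It was followed by regions in an exon of Lars2 (chromosome 9, 123461901 to 123462120; 74.1 and 53.3) and an intron of Il31ra (chromosome 13, 112578161 to 112578320; 65.8 and 46.7). Of the 10 strongest, 8 had a further copy in the assembly, as did 10 of 200 random shared regions. The exceptions were regions at Hjurp and Mplkip, 2 bp and 191 bp from their transcript starts. Outside promoters the next strongest were the intergenic regions nearest to Igf2bp3 (chromosome 6, 49236421 to 49236620; 67.7 and 42.7) and Gm8797 (chromosome 3, 5860361 to 5860530; 59.3 and 42.9), which also rank among these 10.

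Shared distal regions were densest around Kdm6b, which encodes a histone H3K27 demethylase, with 11 regions or 19.9 per 100 kb of domain, against a median of 0.896 over 14149 domains of at least 50 kb. Fmod followed with 19.6, the clock gene Per1 with 18.3, and Klrb1c and Klrb1b, which encode receptors of natural killer cells, with 17.7 and 17.1. Trim7, Adamtsl4, Ctc1, Osbp and Trim27 had 14.5 to 16.6. The domains of Per1, Trim7, Ctc1, Osbp and Trim27 also held 7 to 10 tRNA genes each.

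Footprints, short stretches within open chromatin that are protected from cutting, numbered 316358 in the library labelled replicate 1 and 270843 in the library labelled replicate 2, with a median width of 10 bp in both. In these libraries 74.0% and 69.5% lay within peaks, and 35.1% (95% Wilson interval 34.9 to 35.2) and 39.4% (39.2 to 39.6) overlapped a footprint of the other. Of those within peaks 40.1% and 46.2% did so, against 17.02 ± 0.0475 (SD, n = 10) and 18.6 ± 0.0764 (SD, n = 10) percent when footprints were placed at random within peaks.

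Consensus sequences of 26 transcription factors were counted in footprints and in the remaining peak sequence. A match had to lie whole within a footprint, and the median footprint was 10 bp wide. Longer sequences could thus be counted only in the wider footprints. Ratios of sequences of different length therefore rest on different sets of footprints, and their sizes are not directly comparable. With this limit, the insulator protein CTCF and the factors NRF1 and REST had the highest ratios. The CTCF consensus was 200 times as frequent per position in footprints as in the rest in the library labelled replicate 1 (95% interval 179 to 223) and 315 times in the library labelled replicate 2 (262 to 378). NRF1 had ratios of 270 and 181, REST of 131 and 225, CRE of 26.2 and 33.5, SP/KLF of 14.1 and 11.7, and YY1 of 10.5 and 4.73. With 20 bp added to each side of the footprints CTCF had 23.8 and 47.5, NRF1 30.8 and 31.8, and REST 10.9 and 16.1. CRE followed with 6.61 and 6.68. Of the 26, 9 were higher and 10 lower in both libraries (Fisher's exact test, two-sided, adjusted p under 0.05 in each). The reversed SP/KLF consensus had ratios of 15.3 and 13.3, but it is a GC box like the motif itself and so is no control for it. Of 20 reversed controls 3 were higher and 10 lower, and footprints had a GC content of 62.4% and 64.3% against 54.1% and 56.5% in the rest.

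Among factors of the T lineage, RUNX was slightly higher in footprints, with ratios of 1.07 (exact adjusted p = 0.00425) and 1.24 (adjusted p = 2.76e-22), and E proteins had 2.25 and 1.08. Reversed, E proteins had 1.12 and 1.29, so that in the library labelled replicate 2 the control was the higher of the pair. In footprints shared by both libraries neither motif was called, with ratios of 1.21 and 0.923 for RUNX and 1.21 and 0.9503 for E proteins. ETS did not pass (1.07 and 1.02; exact adjusted p = 0.0653 and 0.556), but was higher in both libraries with 20 bp added to each side of the footprints (1.40 and 1.36; adjusted p = 1.07e-65 and 5.1e-57) and lower in both in distal peaks (0.422 and 0.484; adjusted p = 1.56e-40 and 9.69e-54). TCF7/LEF1 was below the rest in the library labelled replicate 1 with 0.566, and its 0.949 in the library labelled replicate 2 did not pass (exact adjusted p = 0.355). It was lower in both libraries in shared footprints (0.415 and 0.518; exact adjusted p = 1.1e-31 and 6.3e-20) and with 20 bp added (0.726 and 0.898). Reversed, it had 0.312 and 0.339, below the motif itself in both libraries. The unreversed TCF7/LEF1 ratio in the library labelled replicate 2 was 1.68 times that in the library labelled replicate 1 (95% interval 1.44 to 1.95). For RUNX the factor was 1.16, but other T lineage motifs went the opposite way, with 0.480 for E proteins, 0.699 for Ikaros and 0.886 for MYB. Of the 26 motifs 4 had a higher and 6 a lower ratio in the library labelled replicate 2 (normal test of the log ratios, adjusted p under 0.05). Lower in footprints of both libraries were MYB (0.871 and 0.771), NF-kB (0.745 and 0.730), IRF (0.501 and 0.564), AP-1 (0.452 and 0.370), GATA (0.369 and 0.321), SOX (0.267 and 0.387), PU.1 (0.292 and 0.338), MEF2 (0.339 and 0.196), OCT (0.291 and 0.233) and GRE (0.121 and 0.0460). Reversed, GATA (0.413 and 0.487), SOX (0.235 and 0.284), PU.1 (0.304 and 0.211), IRF (0.337 and 0.489) and OCT (0 and 0) were low as well, while MYB (1.07 and 0.951) and NF-kB (2.44 and 2.72) were not, and AP-1, MEF2 and GRE had no such control. With 20 bp added to the footprints MYB, IRF, GATA and SOX stayed lower in both libraries, NF-kB, AP-1, PU.1, MEF2, OCT and GRE were no longer called, and OCT had a mean ratio of 1.11. RUNX was then no longer called higher (0.971 and 1.11).

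**Figure D4:**
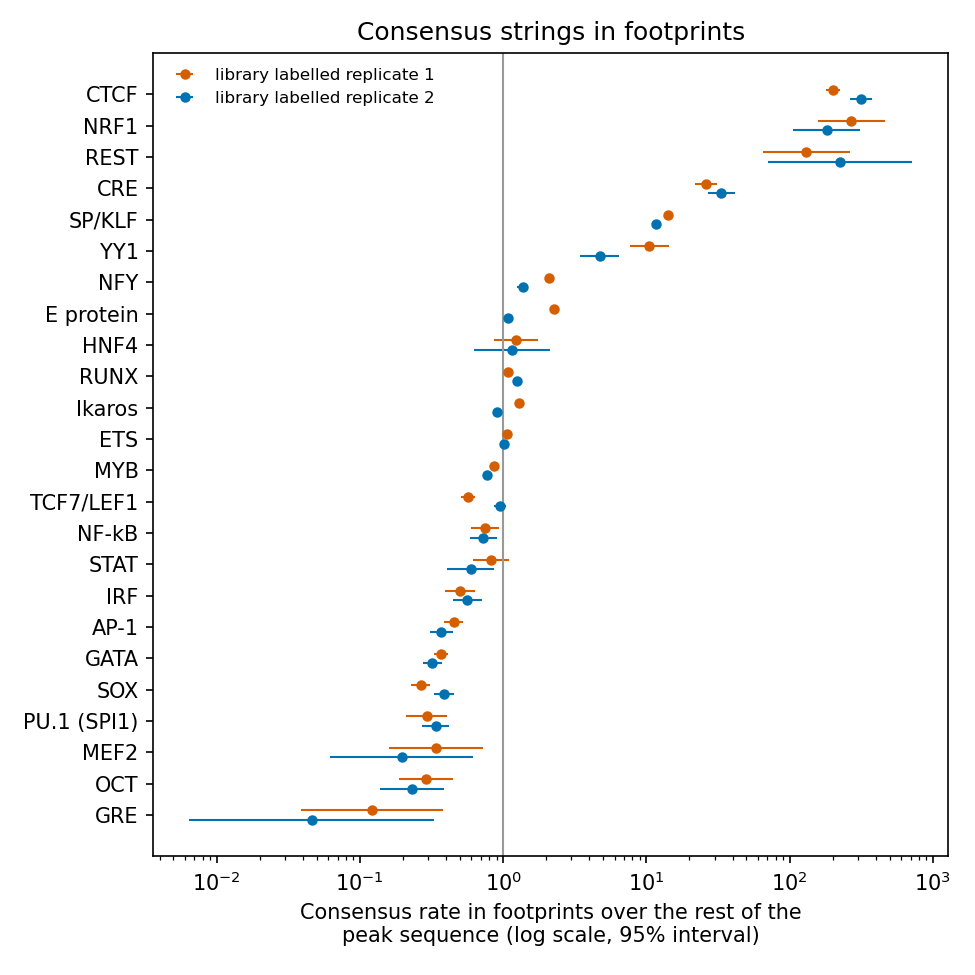
Frequency of consensus sequences in footprints over that in the remaining peak sequence, per library, with 95% intervals on a log axis; 2 of the 26 sequences are not drawn. CTCF reached 200 and 315 in the libraries labelled replicate 1 and 2, and GRE 0.121 and 0.0460.

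The X chromosome, present as a single copy in males, held 964 shared regions or 5.64 per Mb, against 13.9 per Mb on the autosomes, a ratio of 0.405. The autosomes ranged from 9.81 per Mb on chromosome 14 to 24.0 on chromosome 11, so the X lay below each of them. The Y chromosome held 11.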

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

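The motif results of each library alone were added after the data were examined; all other alternatives were planned. Of 400 recomputed values 333 stayed the same, 23 moved, 20 lost and 17 gained significance and 7 reversed. Staying the same meant keeping the direction and side of the threshold or staying within the spread. For the number of motifs called higher it meant staying within a fixed fold range. The causes were not tested. The largest dependence was on which library was counted. With each library alone, open promoters ranged from 21.1% to 94.7% for T cell receptor and coreceptor genes and from 50% to 93.8% for thymocyte development, and both lists reversed against other genes without the library labelled replicate 1. The range was 5.56% to 38.9% for effector T cells, 25% to 41.7% for endothelium, 16.7% to 33.3% for pluripotency and germ line, and 0% to 54.5% for liver. The number of lists with more distal peaks ranged from 0 to 3, and the median distal peaks from 2 to 7 for T cell receptor and coreceptor genes, 3 to 11 for T lineage transcription factors and 2.5 to 3.5 for thymocyte development. Promoters held 36.7% to 41.4% of the peaks of a library, intergenic sequence 24.999% to 26.0%, and the X ratio was 0.363 to 0.366.

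Overlap was 35.5% and 49.9% in the libraries labelled replicate 1 and 2 with 50% reciprocal overlap, 49.8% and 70.2% for the stronger 50% of peaks, 53.6% and 53.7% for equal numbers of peaks and 37.8% and 54.3% for the longer lists. Shared footprints fell to 24.4% and 28.5% with 50% reciprocal overlap. Shared regions at promoters were 43.6% with 500 bp windows, 60.3% with 2500 bp and 63.1% for the stronger 50% of peaks, and intergenic ones 24.5%, 20.1% and 18.2%. With 2500 bp windows myeloid and dendritic cell (33.3%) and liver genes (27.3%) no longer passed. Among the stronger 50% of peaks T lineage transcription factors (72.2%) no longer passed and thymic epithelium (18.8%) did. With the longer lists T cell receptor and coreceptor (36.8%) and endothelium (33.3%) no longer passed, and with the gene 5' end alone fibroblast and mural cell (16.7%) did.

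Motif ratios reversed for Ikaros (0.798 in shared footprints; 0.905 to 1.30 with each library alone), OCT (1.11 with 20 bp added), and ETS (0.453) and NFY (0.826) in distal peaks. REST had no mean ratio with the background within 50 bp, since that of the library labelled replicate 2 held no occurrence, but passed in both libraries (Fisher's exact test, adjusted p = 8.89e-59 and 1.69e-53). The planned choice of footprints by score was not run because the score is constant. Unknown depth limits all comparisons of peak and footprint numbers between the libraries.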

Other observations

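Chosen after the result was seen were the motif counts in unshared distal peaks, the test of peak calling and the second test of a mixture; the decision to test other tissues at all was also made after the libraries were seen to differ, with kidney as the first guess.

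Distal peaks found in 1 library only differed in sequence. Those of the library labelled replicate 2 (17362 peaks) held, among others, the consensus of PU.1 3.96 times, of ETS 3.09 times, of NRF1 2.91 times, of SP/KLF 2.12 times, of RUNX 2.00 times and of TCF7/LEF1 1.28 times as often per position as those of the library labelled replicate 1 (34748 peaks). More frequent in the latter were, among others, HNF4 at 5.08 times (95% interval 3.31 to 7.79) and GATA at 1.75 times. Of 26 motifs 11 were higher in the library labelled replicate 2, 9 in the library labelled replicate 1 and 6 did not differ (Fisher's exact test, two-sided, adjusted over the 26). GC content was 53.2% and 50.4%.

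Of the 13 lists of other tissues, pancreas alone had more distal peaks than matched random lists in the library labelled replicate 1, with a median of 11 against 1 (permutation test, adjusted p = 0.00260 over 13 lists, from the smallest p the permutations can give). In the library labelled replicate 2 its median was 0.5 (permutation test, adjusted p = 0.979). Medians in the libraries labelled replicate 1 and 2 were 3 and 3 for stomach (permutation test, adjusted p = 0.173 and 0.0780), 2.5 and 1.5 for lung, 2 and 0.5 for heart, 2.5 and 2 for kidney, 3 and 1 for small intestine, 2 and 2 for adrenal gland, liver and neuron, 2 and 0 for skeletal muscle, 1.5 and 1.5 for adipose tissue, 1.5 and 0.5 for epidermis, and 2 and 1.5 for glia. Promoters of the 14 pancreas genes were open in 11 cases in the library labelled replicate 1 and in 3 in the library labelled replicate 2. Of all protein-coding genes 63.1% and 60.1% were open in these libraries, and the pancreas promoters were not tested against them. Of the 14, 0 are in the 17 lists fixed in advance, and their expression in thymus was not measured here, although medullary thymic epithelium is known to express many tissue-restricted genes, pancreatic ones among them. Genes of abundant pancreatic enzymes had promoter signals in the library labelled replicate 1 of 4.92 at Pnlip, 5.86 at Cela2a, 5.92 at Cela1, 8.19 at Ctrb1 and 4.22 at Cpa1, and 38, 24, 24, 12 and 11 distal peaks, against 0, 2, 5, 1 and 0 in the library labelled replicate 2. The Cela1 promoter was also open in the library labelled replicate 2, with a signal of 5.10. Pnlip, Cela2a, Ctrb1 and Cpa1 had no promoter peak there. Amy2a5, Ins2 and Gcg had no promoter peak in either library.

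T cell sites had peaks in the library labelled replicate 2 that the library labelled replicate 1 lacked. The library labelled replicate 1 did not have fewer open promoters among all genes (13822 against 13158). Of 22 such promoters, 3 (13.6%, interval 4.75 to 33.3) had a peak in its longer list. Of all unshared peaks of the library labelled replicate 2, 15.1% did, so the low share was not particular to these promoters. The library labelled replicate 1 had more peaks in the shorter list (85367 against 60644) and in the longer (126824 against 88164). Peaks of its shorter list reached an FDR of at most 0.000999, against 0.000994. These values argue against fewer or stricter peak calls as the cause at these 22 promoters. Depth is unknown and was not weighed here. Pancreas genes gained a mean of 10.1 more distal peaks than genes of 5 thymus cell types (permutation test, p = 0.000260 after multiplying by 13 lists). Pancreas was picked as the list leading in the library labelled replicate 1, and its gain can go with a lower share of thymocytes. The test therefore cannot exclude a lower share of thymocytes among the cell types of the thymus itself. A candidate explanation is that the library labelled replicate 1 was made mostly from another tissue such as pancreas. Its prediction asked that a list of another tissue pass in that library alone and no thymocyte list pass there. The pancreas list met it, with a median of 11 distal peaks. The libraries had by then been seen to differ at T cell genes, so the part on thymocyte lists was no independent check. A swapped sample, neighbouring tissue taken at dissection and a difference between the animals were not tested apart. What share of the library labelled replicate 1 came from another tissue, if any, was not estimated. Whether thymocytes were a large part of it stayed undecided: the test written in advance favoured a mixture, with 92.3% (12 of 13) of the strongest distal sites present, and only after it was found that 96.8% of other strong sites were present too was a wider set tested, where 35.4% (75 of 212, interval 29.3 to 42.0) were, against 73.0% of other sites.

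The strongest shared regions may reflect reads of multi-copy sequence placed at single sites. A further copy was found for 8 of 10, against 10 of 200 random shared regions (5.00%; Fisher's exact test, two-sided, p = 2.20e-08). No biological explanation was tested.

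The densest distal domains may in part mark tRNA genes, whose starts are not among the annotated transcript starts. Over all 10 domains 42.2% of 90 distal regions (38; interval 32.5 to 52.5) lay within 500 bp of a tRNA gene, against 0.839% of other distal regions (Fisher's exact test, two-sided, p = 3.35e-52), a value between the bounds set in advance. Of the 10 domains 5, those of Kdm6b, Fmod, Klrb1c, Klrb1b and Adamtsl4, hold no annotated tRNA gene. No biological explanation was tested.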
